A study of Mus musculus with 2 samples.

How the data were processed

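Cells positive for CD45 and F4/80 were sorted from perfused, collagenase-digested BALB/c livers after hepatocytes had been spun out, and 1 library was made from vehicle-treated and 1 from CCl4-treated mice with a 10x Genomics Chromium 3′ kit, per the labels' protocols. How many mice were pooled in each library was not given in the sources used here. The submitters' processing notes name Cell Ranger 3.1.0 and the mm10 build. They give no role or setting for either, and the cell-calling settings and the annotation release were not given in the sources used here. As deposited, the 4 files used hold text only: for each library a list of cell barcodes and a list of genes with an ID, a symbol and a feature type. Neither kind of file holds a measured value, so no normalisation applies and no count model, clustering, doublet caller or comparison of expression was run. Count tables were not analysed here. The comparisons of cell type shares and of summed counts that had been planned for such tables were not run.

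Samples were grouped by the treatment in their labels. With 1 library per group there was no test between groups. Barcodes were compared as 16-base strings, without the suffix that is the same on every line. The number of shared barcodes is given with an exact Poisson 95% interval. The chance value was derived from the lists themselves. Every barcode was split after base 4 to base 12, and the split with the fewest possible combinations of distinct parts, after base 7, was used. The number of shared barcodes expected by chance is the product of the numbers of library-to-library pairs that share the first part and the last part, divided by the number of all pairs. For the simulations, the last parts were permuted against the first parts within each library 1000 times with a fixed seed. The split was chosen from the numbers of distinct parts, not from the overlap, but after the data had been seen. The calculation with the split after base 7 was tested on simulated lists of the same lengths, 20 runs each. Those lists were built from freely combining parts of 7 and 9 bases, so the choice of split was not tested. With 0 planted shared barcodes the excess found was -1.7 ± 15.0 (SD), and with 200 planted it was 198.2 ± 14.2.

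Gene IDs were matched without version to GENCODE M21 (GRCm38), whose gene coordinates and classes are given. Symbols of the prepared-list genes and sort antigens with a row are those of the deposited gene lists. Genes without a row, and genes named as sharing sequence with a prepared-list gene, carry their M21 symbols. Of the matched IDs, 733 carry another symbol in M21, and 0 of these have a prepared-list gene as their deposited symbol. Genes of the prepared lists were looked up by symbol. In the deposited lists, 38 symbols stand on more than 1 row. Before the data were examined, 10 lists of macrophage functions and 16 lists of cell type markers, 153 distinct genes in all, were fixed for naming genes, together with the rule that without count tables they would serve only to say how many members have exactly 1 row; 152 did. Ptprc and Adgre1 were added as the sort antigens, which gave 154 genes with a row. For these, every distinct 50-base window in the last 500 bases of the gene's protein-coding transcripts was searched, on the transcript strand, in all M21 transcripts of the other listed genes. This search was added after the files had been seen and was tested on simulated transcripts with a planted copy. Windows of 90 bases and the last 300 bases were tried as alternatives. The read length of the libraries was not given in the sources used here. The computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.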

Results

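The series set out to compare liver macrophages from BALB/c mice given carbon tetrachloride (CCl4), a hepatotoxin used to produce liver fibrosis in rodents, with those from mice given vehicle. Nonparenchymal liver cells were stained for CD45, the pan-leukocyte antigen encoded by Ptprc, and for F4/80, the macrophage antigen encoded by Adgre1. Live double-positive cells were sorted and made into droplet single-cell libraries with a 10x Genomics Chromium 3′ kit. There were 2 libraries, 1 vehicle and 1 CCl4, so neither group had replicates and no difference between the groups could be tested. Count tables were not analysed here. No gene, cell type or cell state therefore has a value below for either library, and whether any gene was higher or lower after CCl4 is not addressed. The files used were the list of cell barcodes and the list of genes of each library. Reads or UMIs per cell, and hence the depth of each library, are unknown.

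The first comparison concerns the number of cell barcodes, the 16-base tags that mark droplets, listed for each group. The vehicle library held 25182 barcodes and the CCl4 library held 21775. Each barcode occurred once in its list. The 2 numbers were each a single observation without a replicate error, so the lower number in the CCl4 library cannot be set against the spread between mice. Each barcode stands for a droplet, and how the listed droplets were selected was not given in the sources used here. A droplet can hold more than 1 cell. Without counts neither doublets nor droplets of free RNA could be removed, so the numbers are not counts of macrophages. Loading of a chosen number of sorted cells also sets such numbers, and the numbers loaded were not given in the sources used here.

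The second comparison asked whether the 2 libraries held the same droplets, as they would if one library had been deposited under both names. They did not: 162 barcodes occurred in both lists, with an exact Poisson 95% interval of 138.0 to 189.0 that covers counting error only. This was 0.643% of the vehicle barcodes and 0.744% of the CCl4 barcodes. The barcodes had a composite structure. Across both lists the first 7 bases took 960 different sequences and the last 9 bases took 3843, which gives 3689280 combinations, of which the 46795 distinct barcodes in the 2 lists used 1.27%. When the first and last parts were taken to combine freely within each library, 149.3 shared barcodes were calculated by chance. Random re-joining of the parts in 1000 simulations gave a mean of 147.9 ± 12.4 (SD), and 144 of the simulations reached 162 or more (two-sided permutation p = 0.290). The observed overlap lay 12.7 above the calculated chance value, about 1 SD of the simulations. With this split, after base 7, the test did not separate the overlap from chance. The chance value depends on the split: it was 37.3 after base 6 and 37.5 after base 8. The split after base 6 cuts base 7 off from the first 6 bases, which fix it in these lists. The split after base 8 cuts base 8 off from the last 8 bases, which fix it.

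**Figure D1:**
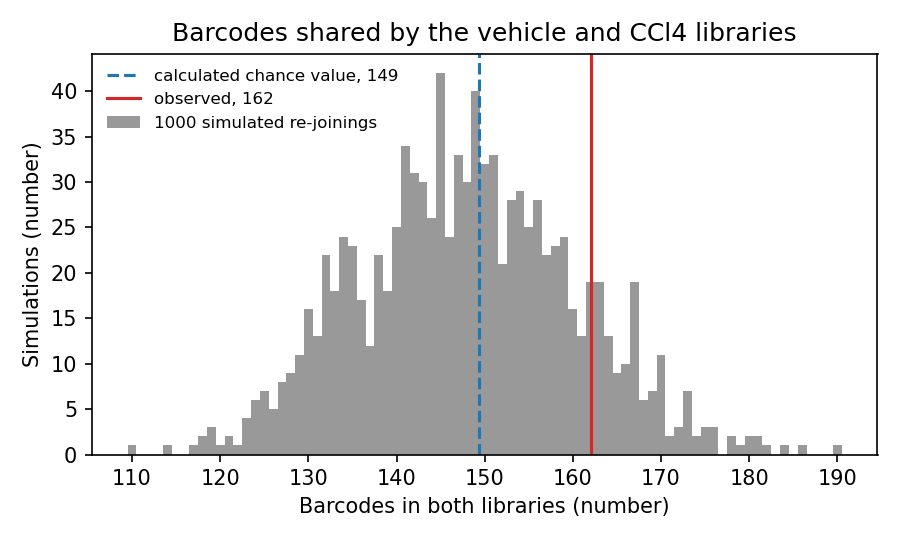
Barcodes found in both libraries. Grey bars give the number of simulations (vertical axis) that produced each number of shared barcodes (horizontal axis) when first and last barcode parts were re-joined at random within each library, the dashed line the calculated chance value of 149.3 and the solid line the observed 162, which lies inside the simulated range of 110 to 190.

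The third comparison asked whether both libraries were counted against the same genes. The gene lists of the vehicle and CCl4 libraries were identical in all 32285 rows and in their order, and all rows were of the gene expression type, with no antibody or hashtag rows. Of these gene IDs, 32235 (99.8%) occur in GENCODE M21, an annotation of the GRCm38 (mm10) mouse assembly, where 21702 of them are protein-coding. The list held 218 immunoglobulin V genes, 144 T cell receptor V genes and 13 mitochondrial genes. The genes of both sort antigens were on it. Ptprc (ENSMUSG00000026395) lies at chromosome 1, positions 138062861 to 138175708, on the minus strand, and Adgre1 (ENSMUSG00000004730) at chromosome 17, positions 57358691 to 57483527, on the plus strand. Coordinates here and below are those of GENCODE M21 on GRCm38.

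The prepared lists for Kupffer cells, the resident macrophages of the liver, and for scar-associated macrophages were complete. This describes the gene list used for counting, not these cells. Among all protein-coding genes of M21, 98.5% had a row, so complete lists were likely for any set of such genes. All 10 members of the Kupffer identity list had exactly 1 row, among them Clec4f (ENSMUSG00000014542, chromosome 6, 83644542 to 83656187), a lectin restricted to Kupffer cells in mice, Vsig4 (ENSMUSG00000044206, chromosome X, 96247203 to 96293438), a complement receptor, and Timd4 (ENSMUSG00000055546, chromosome 11, 46810800 to 46844332), a phosphatidylserine receptor. All 10 members of the lipid- and scar-associated macrophage list also had 1 row, including Trem2 (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147), a lipid-sensing receptor, Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), which encodes osteopontin, and Gpnmb (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929). The same held for the 10 matrix remodelling genes, the 10 inflammatory cytokines and chemokines, the 8 growth factors, the 10 complement and efferocytosis genes, the 6 iron handling genes and the 8 dissociation stress genes. None of the genes in the Kupffer identity, scar-associated, matrix remodelling, cytokine, growth factor and complement lists had 10% or more of its 3′ sequence in another listed gene. That holds for M21 sequence, and BALB/c sequence was not examined.

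The interferon response list was the only prepared list with a member missing. Of its 8 genes, 7 had a row and Mx1 (ENSMUSG00000000386, chromosome 16, 97447035 to 97462907), an interferon-induced antiviral GTPase, had none under that symbol. Its ID was not checked separately. All 8 antigen presentation genes had a row, including the MHC class II genes H2-Aa (chromosome 17, 34282744 to 34287823), H2-Ab1 (34257689 to 34269419) and H2-Eb1 (34305867 to 34316674). H2-Ea-ps (ENSMUSG00000036322, chromosome 17, 34341959 to 34344645), the locus of the I-E alpha chain that pairs with the product of H2-Eb1, had no row. H2-Ea-ps was not on a prepared list and was looked up after the gene list had been seen.

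**Figure D2:**
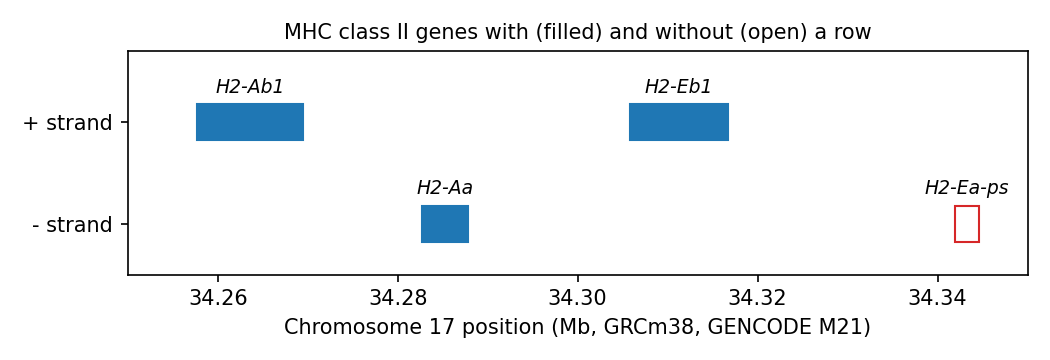
Map of 4 MHC class II genes on mouse chromosome 17 (GRCm38, GENCODE M21), with position in Mb on the horizontal axis and the strand on the vertical axis; other genes of the interval are not drawn. Filled boxes are the 3 genes with a row in the gene lists (H2-Ab1, H2-Aa, H2-Eb1) and the open box is H2-Ea-ps, which has none.

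Each member of the 16 cell type marker lists had a row, against 98.5% of all protein-coding genes of M21. These lists covered liver macrophages (Kupffer cell and monocyte-derived macrophage), other leukocytes (monocyte, conventional and plasmacytoid dendritic cell, neutrophil, eosinophil, B cell, T cell and NK cell), cells that a CD45 sort would be meant to remove (endothelial cell, stellate cell, hepatocyte, cholangiocyte and erythroid cell) and cycling cells. Some of these markers shared transcript sequence with a close relative. The share was measured over windows of 50 bases in the last 500 bases of each coding transcript, pooled over the annotated coding transcripts of a gene. Which of these transcript ends the libraries held is unknown. M21 annotates the mouse reference genome, which is not from BALB/c, the strain used here. The shares are therefore those of the reference genes. The sequences and gene copies of BALB/c were not examined, so the shares in these libraries may differ. Among 154 genes, 19 had at least 1 window in another listed gene, 11 had 10% or more and 4 had 50% or more. Hba-a1, an alpha globin gene used as an erythroid marker, shared 88.9% of its windows with Hba-a2. Hbb-bs, a beta globin gene, shared 60.9% with Hbb-bt. Ftl1, the ferritin light chain, shared 69.9% with Ftl1-ps1, and Oas1a, an interferon-induced oligoadenylate synthetase, shared 56.1% with Oas1g. The Oas1a value depended on the part searched: it was 42.3% with windows of 90 bases and 21.1% over the last 300 bases.

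Further genes of the prepared lists also shared sequence with other listed genes. Ly6c2 (ENSMUSG00000022584, chromosome 15, 75108158 to 75111970), which marks inflammatory monocytes, shared 34.8% of its windows, mostly with Ly6c1, and 19.3% with windows of 90 bases. Clec10a, a lectin of dendritic cells and macrophages, shared 15.6% with Mgl2, and Chil3, a chitinase-like protein of monocytes, shared 15.4% with Chil4; with windows of 90 bases these fell to 7.66% and 8.06%. Serpina1a, a hepatocyte protease inhibitor, shared 42.8% with 4 other listed genes, chiefly Serpina1c. Its share was 30.2% with windows of 90 bases and 58.7% over the last 300 bases. Ifit3 shared 14.9% with Ifit3b, but 6.57% with windows of 90 bases and 0.398% over the last 300 bases. For Cyp2e1 and Csf3r the shared windows, 83 of 692 and 52 of 452, matched 100 and 169 listed genes respectively. With windows of 90 bases, 37 of 652 windows of Cyp2e1 matched 6 genes and 0 of 412 windows of Csf3r matched any, whereas over the last 300 bases the shares were 16.9% for Cyp2e1 and 20.6% for Csf3r. Hspa1a and Hspa1b, the paired heat shock genes of the dissociation stress list, shared 0.0% over this part of their transcripts. Hba-a1, Hbb-bs and Ftl1 shared over 50% of their windows in each of the 3 searches. By M21 sequence, a read that lies within a shared window fits more than 1 gene. Whether it would do so by BALB/c sequence was not examined. How such reads were treated was not examined here.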

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

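Of 9 alternatives, 4 were planned and 5 were chosen after the data had been seen; 5 stayed within 1.5 times the reported value and 4 did not. Leaving out the shared barcodes gave 25020 for the vehicle and 21613 for the CCl4 library, and counting only unique symbols gave 32207 genes. These alternatives could hardly move the values, since they left out only 162 barcodes per library or 78 rows. Counting pairs of barcodes that differ at exactly 1 base, in place of exact matches, gave 0 between the libraries; that alternative has little to find, since 0 pairs of first parts and 4 pairs of last parts differ at 1 base. The chance number of shared barcodes was 37.3 with the barcode split after base 6 and 37.5 with the split after base 8. Those splits each cut a base off from the part that fixes it. The first 6 bases fix the seventh (960 sequences for either length), and the last 8 fix the one before them (3843 for either length). The pool size was 3384803 when estimated from the shared barcodes (95% interval 2901929 to 3973062) against 3689280 from the parts. That comparison restates the one between the shared barcodes and their chance number, so it is not a separate check. With windows of 90 bases, 6 rather than 11 genes shared 10% or more of their 3′ windows, and 10 did so over the last 300 bases. The planned comparisons of cell class shares and of summed counts, with their alternatives of cell filter, clustering resolution, doublet removal and scaling, were not run, since count tables were not analysed here. No leave-one-out value exists with 1 library per group. Depth could not be assessed in either library.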

Other observations

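All tests in this part were chosen after the results they bear on had been seen. Genes that macrophages or inflamed liver can express were among those without a row. Polymorphic pseudogenes are a GENCODE class for loci annotated as intact in some strains or individuals and disrupted in the reference, which for mouse is C57BL/6J. The class alone does not show that a given locus is disrupted, and this was not examined. M21 holds 82 polymorphic pseudogenes, and 0 of the 82 had a row under their ID or symbol. Of these, 59 carry olfactory or vomeronasal receptor symbols and 23 do not. Among the 23 are Clec7a (ENSMUSG00000079293, chromosome 6, 129461591 to 129472779), which encodes the beta-glucan receptor Dectin-1, Cxcl11 (chromosome 5, 92359544 to 92365485), an interferon-induced chemokine, Pla2g2a (chromosome 4, 138831857 to 138835186), a secreted phospholipase, Mmp1a, an interstitial collagenase, Mx2, Oas1b and Gbp11, which belong to interferon-induced families, and the MHC loci H2-Ea-ps, H2-Q5, H2-T10 and H2-Bl. As background, C57BL/6 mice lack a functional I-E alpha chain and a functional Pla2g2a while BALB/c mice, the strain used here, have both. Their transcripts in these libraries would not be counted under this gene list.

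A candidate explanation for this gap is a filter on annotation class when the gene list was made. It was tested on the other 27 classes of M21 with at least 20 genes: in 15 of them under 5% of the genes had a row, in 12 over 90% had one, and 0 lay between. Of the 55348 genes in these classes, 98.8% had or lacked a row as the majority of their class did, which is consistent with such a filter; what was done to make the list was not given in the sources used here. Among the 326 protein-coding genes without a row, 218 (66.9%) have only readthrough transcripts, which join neighbouring genes, against 1 of the 21702 with a row, so removal of genes with readthrough transcripts only is a candidate explanation for most of these. Another 46 genes that have both readthrough and other transcripts kept a row. For 19 of the 326 the symbol stands on a row under another ID. Removal of genes with readthrough transcripts only cannot account for Mx1, which is protein-coding in M21 and has 0 readthrough transcripts. A row for Mx1 under another symbol was not looked for. A different class in the release the list was made from stays open, since that release was not used here. Of the IDs on the list, 50 are absent from M21.

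For the 162 barcodes found in both libraries, carry-over between the libraries was not needed as the source of most of them: with the barcode split after base 7, the upper 95% limit of the excess over chance was 39.6 barcodes, below the 81 that most would need. This call depends on the split. With every other split tried, after base 4 to base 12, the upper limit would be 145.2 to 178.5, above those 81. The excess itself would be 118.2 to 151.6 with those splits, and 124.7 or 124.5 with the splits after base 6 or 8. Every other split gave more possible combinations of distinct parts than the split after base 7. The splits after base 6 and 8 each cut a base off from the part that fixes it. In these lists the first 6 bases fix the seventh and the last 8 fix the one before them. Independent draws from one barcode pool may account for the overlap, as the 149.3 barcodes calculated under that model with the split after base 7 lie within the interval of 138.0 to 189.0 around the observed number. Carry-over of fewer barcodes, up to 0.182% of the CCl4 list, stays open. No biological explanation was tested.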
